A study of Mus musculus with 6 samples.

How the data were processed

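The series holds 6 libraries of mouse heart RNA, 3 from control mice and 3 from mice given ISO+L-NAME for 6 weeks. Per the labels' protocols, total RNA was isolated with Trizol and libraries were made with a QuantSeq forward kit, which reads from the 3′ end of polyadenylated messages, so a gene's count does not grow with its length. The submitters' processing notes name bcl2fastq and the genome build GRCm39; the aligner, the counter, the annotation release and the use of strand or molecular identifiers are not given in the sources used here. Overlapping genes and near-identical copies are therefore uncertain. The exact intervals of count ratios cover counting error only, and the bootstrap intervals cover the spread between genes only.

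The authors deposited whole-number counts per gene for each library, per the file headers, and beside them a scaled signal that the headers call CPM. In the deposited table each scaled signal column is the count column times 1 constant and the columns sum to different totals, from 789185 in ISO+L-NAME 1, so it was used only as an alternative set of library sizes. Of 25361 genes, 10824 had no count in any library. Coordinates are the file's own, on GRCm39. The reference annotation in hand is of another build and was used only for names: 25268 of the gene identifiers were found in it. The 40 names with a number suffix were matched to lists without it.

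Total counts per library were 2448484, 2347139 and 2217974 in controls and 2637364, 2354157 and 2374361 in treated hearts. Replicates were checked for duplication: within groups the chi-square per degree of freedom between libraries ran from 2.10 to 3.42, so none agreed within sampling noise. Genes were filtered with filterByExpr at its defaults (minimum count 10, minimum total 15), scaled by TMM (factors 0.857 to 1.15) and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, 1 factor for group, Benjamini-Hochberg threshold 0.05). Standard errors are the absolute log2 change over the square root of F. CPM in the text is counts scaled to TMM-adjusted library sizes. For genes with 1 to 3 counts over the controls, the ratio of pooled counts is given with a 95% exact (Clopper-Pearson) interval.

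The 39 gene lists, the design and the rule for named genes were written before the data were examined. Lists with at least 3 tested members were tested two-sided with camera from limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives; fry asks whether a list's genes move one way on balance and does not compare them with other genes. Some genes belong to 2 lists, among them Mfap5, Dcn, Mt1, Mt2, Per1, Atf3, Nppa and Nos3. The rule named the 12 genes with the largest increase and the 12 with the largest decrease among genes past the threshold, with a mean of at least 5 CPM and no overlap between groups. It added up to 4 members of each called list with the smallest p in the direction of the call, up to 2 members called the other way, up to 2 called members of each uncalled list, and 16 genes fixed in advance: Nppa, Nppb, Myh7, Myh6, Acta1, Col1a1, Col3a1, Postn, Timp1, Atp2a2, Pln, Nos3, Adrb1, Xbp1, Pdk4 and Gapdh. Some genes that met the rule are not reported here. Shares of counts were compared with exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3.

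The alternatives were RLE scaling, total counts alone, no filter, a mean of at least 5 CPM, a robust fit, DESeq2 1.42.0, limma-voom, mitochondrial genes left out, the replicate number as a block and each library left out in turn. The deposited library sizes were added after seeing the data. The pseudocount and quantile settings planned for a table without counts were not needed. The gene test was tested on simulated counts for this comparison with 8531 genes, of which 200 changed: it recovered 25.8% of 1.5-fold, 69.0% of 2-fold and 95.0% of 4-fold changes, 0 with the wrong sign, and 5.40% of calls were false. The list test called 10 of 10 shifted lists and 0 of 300 unshifted ones, in simulations where genes varied independently.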

Results

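Hearts of 12-week-old male mice were profiled by 3′-end RNA sequencing, with 3 control hearts and 3 hearts taken after 6 weeks of ISO+L-NAME, a combination used to model a form of heart failure abbreviated HFpEF in the series title. L-NAME inhibits nitric oxide synthase. Each library held between 2217974 and 2637364 counted reads over 25361 listed genes, and 8531 genes had enough counts to be tested. The single comparison asks which messages differ between treated and control hearts. Fold changes are log2 of ISO+L-NAME over control with their standard error (SE). Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and are written as edgeR adjusted p, and those of gene lists come from camera with Benjamini-Hochberg adjustment.

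Treated hearts carried more extracellular matrix, macrophage and clock-controlled messages, and fewer messages of the mitochondrial genome, fatty acid oxidation and part of the contractile apparatus, by a list test that called 0 lists once the correlation between genes was estimated from the data (smallest camera adjusted p = 0.150). In all, 520 genes changed, 291 higher and 229 lower, and 189 of them by at least 2-fold (142 higher, 47 lower). Of the changed genes, 512 (98.5%) had no overlap between the values of the 2 groups, a separation the test itself selects for; among the other tested genes it was 17.8%, where unselected genes would give 10% by chance. The common biological coefficient of variation was 10.8%. The classical stress markers did not pass the test: the natriuretic peptide genes Nppa and Nppb differed by 0.01 ± 0.25 and 0.24 ± 0.25 (edgeR adjusted p = 0.994 and 0.702), Myh7 by 0.22 ± 0.26 and Acta1 by 0.21 ± 0.42 (edgeR adjusted p = 0.740 and 0.871). With scaling by total counts alone, 1479 genes passed, 1407 of them higher (95.1%, against 56.0%). The median log2 change of all genes lay 0.30 above that of the TMM scaling. Which scaling is nearer the truth was not tested. Without control 1, 301 genes passed.

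The 12 largest increases that met the rule for named genes were led by 2 genes with almost no counts in controls. Snhg11, a small nucleolar RNA host gene (ENSMUSG00000044349) on chromosome 2 (158217558 to 158228071), had 3 counts over the control libraries and 155 over the treated ones, a ratio of 39.8 (95% exact interval 13.4 to 195). Cdo1, cysteine dioxygenase (ENSMUSG00000033022), on chromosome 18 (46846260 to 46861462), had 2 and 102 counts, a ratio of 39.3 (10.6 to 329). Timp1, an inhibitor of matrix metalloproteinases (ENSMUSG00000001131) on chromosome X (20736405 to 20740974), rose from 0.808 ± 0.999 to 20.2 ± 8.34 CPM (SD, n = 3; log2 4.57 ± 0.52, edgeR adjusted p = 1.08e-05). Serpina3n, an acute-phase serine protease inhibitor, rose by 3.55 ± 0.38, the uncharacterised AI593442 by 3.58 ± 0.52 and Ms4a6c by 3.07 ± 0.47 (edgeR adjusted p = 7.56e-06, 0.000115 and 0.000199). Neb, which encodes the giant thin-filament protein nebulin, rose by 2.46 ± 0.33 (edgeR adjusted p = 5.60e-05). The remaining 5 of these, Cilp, Lgals3, Ciart, Mt2 and Postn, stand with their lists. Without control 2, Cdo1 had 0 counts in controls and no ratio is given. Leaving out 1 library moved some sizes by over 1.5 times, though not the calls: without control 2 the log2 change was 6.08 for Snhg11 and 3.06 for Neb, and for Timp1 it was 3.98 without control 1 and 6.12 without control 3.

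The 12 largest decreases included Scgb1c1, a secretoglobin (ENSMUSG00000038801), at 63, 59 and 35 counts in controls and 15, 11 and 10 in treated hearts (log2 -2.49 ± 0.28, edgeR adjusted p = 9.34e-06; chromosome 7, 140425460 to 140426682). Tmem82 changed by -2.78 ± 0.46, or by -3.65 without ISO+L-NAME 1, and Lgr6, a receptor for R-spondins, by -1.58 ± 0.23 (edgeR adjusted p = 0.000518 and 0.000115). Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum, and Mylk4, a kinase of the myosin light chain kinase family, changed by -1.44 ± 0.15 and -1.40 ± 0.18 (edgeR adjusted p = 5.04e-06 and 4.30e-05). Lsmem1 changed by -1.39 ± 0.19, the galectin gene Lgals4 by -1.64 ± 0.27 and the homeobox gene Cux2 by -1.75 ± 0.34 (edgeR adjusted p = 8.73e-05, 0.000466 and 0.00265). The histone gene H2ac19 changed by -1.55 ± 0.29 (edgeR adjusted p = 0.00171). It belongs to a family of near-identical copies, so its counts may be split or shared. Mdga1 and Fam81a changed by -1.77 ± 0.39 and -1.54 ± 0.38 (edgeR adjusted p = 0.00695 and 0.0171). Mdga1 lost its call without control 1 (edgeR adjusted p = 0.0711), and Fam81a without control 3, ISO+L-NAME 1 or ISO+L-NAME 2 (0.0833 to 0.0943). DESeq2 did not call Fam81a.

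**Figure D1:**
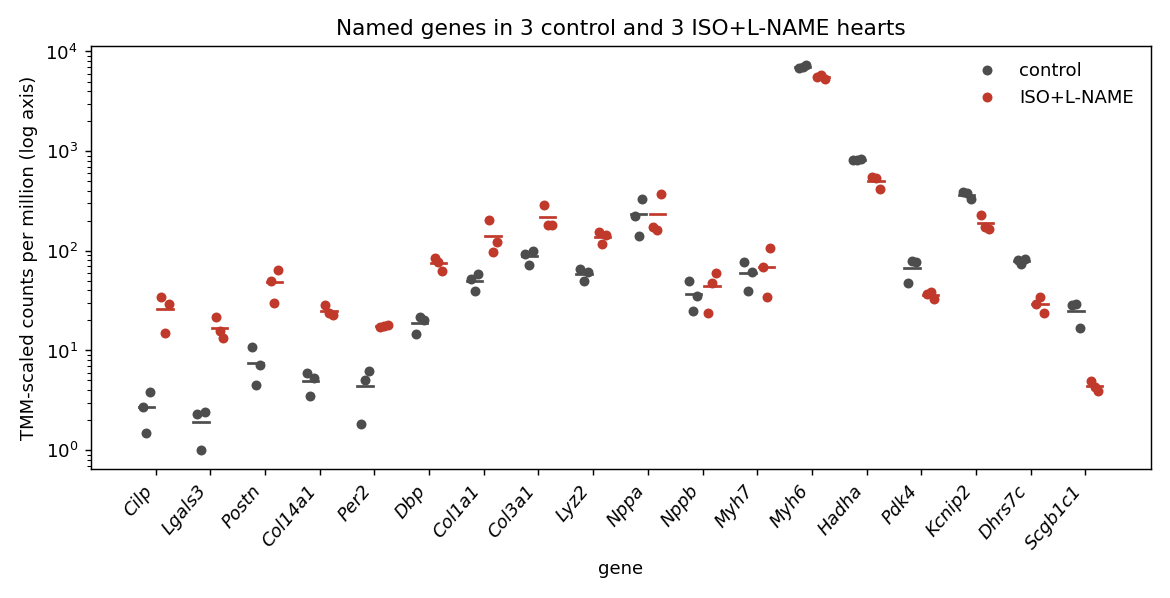
TMM-scaled CPM (log axis) of 18 named genes, with 1 point per library (3 control, 3 ISO+L-NAME) and a bar at each group mean. Postn and Col1a1 sit higher in every treated heart, Scgb1c1 and Dhrs7c lower, and the groups overlap for Nppa, Nppb and Myh7.

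Of 39 gene lists fixed before the data were examined, 32 had at least 3 tested members, and camera with its preset correlation of 0.01 called 14, of which 9 were higher and 5 lower. With the correlation estimated from the data it called 0, the smallest adjusted p being 0.150, with 6 lists at an unadjusted p under 0.05; fry called 5. Other splits of the same 6 libraries gave up to 13 list calls.

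Extracellular matrix and fibrosis genes were called higher. Of 39 tested members, 21 were higher, 1 was lower and 17 were not called (28 higher and 1 lower adjusted over the list alone), with a median log2 change of 1.00 (camera adjusted p = 8.43e-30). The call was lost at an adjusted p = 0.150 with an estimated correlation, and fry, with an adjusted p of 0.0581, did not call the list. Postn, which encodes the matricellular protein periostin (ENSMUSG00000027750, chromosome 3, 54268530 to 54298458), rose from 7.56 ± 3.24 to 48.4 ± 17.4 CPM (SD, n = 3; log2 2.66 ± 0.29, edgeR adjusted p = 7.78e-06). Col14a1 rose by 2.33 ± 0.25 and Cilp, a cartilage matrix protein gene, by 3.26 ± 0.37 (edgeR adjusted p = 7.78e-06 and 1.07e-05). The fibrillar collagen gene Col1a1 rose 2.82-fold, from 49.9 ± 9.70 to 141 ± 54.6 CPM (SD, n = 3), and Col3a1 by 1.29 ± 0.16 (edgeR adjusted p = 7.47e-05 and 3.43e-05), although a robust dispersion fit did not call Col1a1 (0.0781). Col5a3, another fibrillar collagen gene, was lower by -1.09 ± 0.26 (edgeR adjusted p = 0.0136), a call lost without control 1, ISO+L-NAME 1 or ISO+L-NAME 3 (0.0640 to 0.0692).

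Fibroblast markers were also called higher, with 2 of 11 tested members higher, 0 lower and 9 not called (3 and 0 adjusted over the list alone; median 0.17, camera adjusted p = 0.00783). The call did not hold at an adjusted p = 0.513 with an estimated correlation, and without control 2 (camera adjusted p = 0.0815). Mfap5, a microfibril protein gene held also by the matrix list, rose by 1.83 ± 0.22 and Pi16 by 1.22 ± 0.27 (edgeR adjusted p = 1.32e-05 and 0.00748), while Dpt and Dcn differed by 0.51 ± 0.17 and 0.29 ± 0.12 without passing (edgeR adjusted p = 0.0909 and 0.211), although total counts called both and an unfiltered fit called Dpt. Endothelial markers were not called (1 of 18 lower, 0 higher; 1 higher and 2 lower adjusted over the list alone; median -0.11, camera adjusted p = 0.147). The water channel gene Aqp1 was lower by -1.07 ± 0.15 (edgeR adjusted p = 0.000105). Smooth muscle and pericyte markers were not called either (1 higher and 1 lower of 14; 1 and 2 adjusted over the list alone; median -0.26, camera adjusted p = 0.144), with Acta2 at 0.62 ± 0.18 and Myh11 at -1.11 ± 0.28 (edgeR adjusted p = 0.0428 and 0.0166). Acta2 lost its call without control 2 or any 1 treated library (0.0569 without ISO+L-NAME 2), with a mean of at least 5 CPM, and in the robust and DESeq2 fits. Myh11 lost it without control 1, ISO+L-NAME 2 or ISO+L-NAME 3 (0.0528 to 0.206) and with total counts. With scaling by total counts alone, the medians of the endothelial and mural lists were 0.19 and 0.05. Both stayed below the median of all genes, an order that a change of scaling leaves almost unaltered by construction. Without a count filter camera called both lists lower (0.0229 and 0.0341). Endothelial markers were also called without control 1 or control 2 (0.0469 and 0.0457) and mural markers without control 2 (0.00414).

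Macrophage and monocyte markers rose, with 8 of 15 tested members higher, 0 lower and 7 not called (11 and 0 adjusted over the list alone; median 0.94, camera adjusted p = 2.62e-14). Camera dropped the list at an adjusted p = 0.150 with an estimated correlation, while fry kept it. Lgals3, which encodes galectin-3, rose by 3.13 ± 0.36 and the lysozyme gene Lyz2 from 59.0 ± 8.05 to 137 ± 19.3 CPM (SD, n = 3; log2 1.22 ± 0.14), with edgeR adjusted p = 1.22e-05 and 1.04e-05. The complement genes C1qb and C1qc rose by 1.14 ± 0.17 and 0.90 ± 0.16 (edgeR adjusted p = 0.000213 and 0.00128). Of 24 listed inflammatory cytokines and NF-kappaB targets, 7 had enough counts to be tested, and Il6, Il1b and Tnf did not. Of the 7, 2 were higher, 0 lower and 5 not called (2 and 0 adjusted over the list alone), with a median of 0.35. Camera called the list higher (adjusted p = 0.0211). That call was lost at an adjusted p = 0.531 with an estimated correlation, without ISO+L-NAME 2 (0.0596), with a mean of at least 5 CPM (0.121) and with total counts (0.0810). The chemokine genes Ccl6 and Ccl9 rose by 0.98 ± 0.24 and 1.65 ± 0.46 (edgeR adjusted p = 0.0164 and 0.0330), and Icam1 and Vcam1 differed by 0.64 ± 0.39 and 0.35 ± 0.25 without passing (0.434 and 0.534). Ccl6 lost its call without control 1, control 2 or ISO+L-NAME 2 (0.0648 to 0.137) and Ccl9 without control 1, ISO+L-NAME 1 or ISO+L-NAME 2 (0.104 to 0.202) and in the DESeq2 and voom fits. The alarmin gene S100a8, the single tested neutrophil and mast cell marker, rose by 2.76 ± 0.56 (edgeR adjusted p = 0.00365), or by 3.71 without control 2. Interferon-stimulated genes were not called (0 of 11 changed, also adjusted over the list alone; median 0.03, mean -0.06, camera adjusted p = 0.677 with direction down).

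Messages of the mitochondrial genome fell. Of 13 tested, 10 were lower, 0 higher and 3 not called (13 lower adjusted over the list alone; median -0.62, camera adjusted p = 1.33e-23). The list was not called at an adjusted p = 0.150 with an estimated correlation, and fry kept it. The mitochondrial share of all counts was 55.1% ± 1.53 in controls and 46.8% ± 1.22 in treated hearts (SD, n = 3), with no overlap, at the smallest two-sided exact permutation p that 3 against 3 can give, 0.1. The complex I message mt-Nd4l changed by -1.19 ± 0.09, mt-Nd5 by -0.82 ± 0.10, mt-Nd4 by -0.64 ± 0.09 and the cytochrome oxidase message mt-Co3 by -0.62 ± 0.08 (edgeR adjusted p = 2.20e-07, 1.82e-05, 5.99e-05 and 5.99e-05). The genes mt-Nd4l and mt-Nd4 overlap on the mitochondrial genome (9877 to 10173 and 10167 to 11544), so reads may be shared. All 13 messages were lower under each scaling tried, with a median of -0.32 on total counts.

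Genes of fatty acid uptake and oxidation fell, with 13 of 30 lower, 0 higher and 17 not called (17 and 0 adjusted over the list alone; median -0.43, camera adjusted p = 1.67e-15). Camera no longer called the list at an adjusted p = 0.150 with an estimated correlation, and fry kept it. With total counts alone the median of the fatty acid list was -0.12, with 1 member higher and 9 lower. The beta-oxidation enzyme genes Hadha, Hadh and Decr1 changed by -0.71 ± 0.11, -0.73 ± 0.11 and -0.84 ± 0.11 (edgeR adjusted p = 0.000199, 0.000224 and 4.41e-05). Etfb, an electron transfer flavoprotein subunit, changed by -0.69 ± 0.10 and Pdk4, a kinase that inhibits pyruvate dehydrogenase, by -0.90 ± 0.17 (edgeR adjusted p = 0.000105 and 0.00189). Nuclear respiratory chain genes were called lower, with 16 of 79 lower, 0 higher and 63 not called (24 and 0 adjusted over the list alone; median -0.18, camera adjusted p = 4.80e-09). That call was lost at an adjusted p = 0.551 with an estimated correlation. Uqcrc1, Cox6a2, Ndufa7 and Ndufa3 changed by -0.51 ± 0.10, -0.48 ± 0.09, -0.55 ± 0.11 and -0.49 ± 0.11 (edgeR adjusted p = 0.00216, 0.00285, 0.00336 and 0.00561). With total counts alone the respiratory chain list had 11 members higher and 0 lower, a median of 0.12, and its call was lost (camera adjusted p = 0.223), as were the calls of those 4 genes. Relative to the median of all genes the respiratory chain median was -0.17 there and -0.18 with the TMM scaling. These values are close by construction, because a change of scaling moves all genes nearly alike.

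Glycolysis and glucose uptake was not called (3 of 21 higher, 0 lower; 3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.349, or 0.0200 with total counts), although Pgam1 and the hexokinase gene Hk1 rose by 0.78 ± 0.13 and 0.81 ± 0.14 (edgeR adjusted p = 0.000476 and 0.000680). Gapdh differed by 0.17 ± 0.12 (edgeR adjusted p = 0.552), and total counts alone called it higher. Ketone and branched-chain amino acid breakdown was not called (1 higher and 4 lower of 21, the same numbers adjusted over the list alone; camera adjusted p = 0.119, or 0.00276 without control 3). Bdh1, a ketone body dehydrogenase gene, rose from 61.0 ± 12.0 to 159 ± 26.4 CPM (SD, n = 3; log2 1.38 ± 0.15), and Bckdha, of the branched-chain keto acid dehydrogenase, changed by -0.83 ± 0.15 (edgeR adjusted p = 7.78e-06 and 0.00146).

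Adult contractile genes were called lower with members in both directions: 7 of 20 lower, 2 higher and 11 not called (11 and 2 adjusted over the list alone; median -0.26, camera adjusted p = 8.10e-05). The contractile call ended at an adjusted p = 0.262 with an estimated correlation, and fry kept it. Myom2, of the sarcomeric M-band, fell from 596 ± 35.0 to 325 ± 5.03 CPM (SD, n = 3; log2 -0.88 ± 0.10, edgeR adjusted p = 1.04e-05). The ventricular light chain genes Myl3 and Myl2 changed by -0.52 ± 0.09 and -0.45 ± 0.09, Tpm1 by -0.46 ± 0.09 and the adult myosin heavy chain gene Myh6 by -0.33 ± 0.09 (edgeR adjusted p = 0.000986, 0.00365, 0.00372 and 0.0272). Tcap and cardiac actin Actc1 rose by 0.62 ± 0.13 and 0.32 ± 0.09 (edgeR adjusted p = 0.00440 and 0.0490). Myh6 lost its call without control 1 or any 1 treated library (0.0593 to 0.139), Tcap without control 1 (0.0711) and Actc1 in every fit without 1 library except ISO+L-NAME 1 (0.0935 to 0.237), with DESeq2, with a mean of at least 5 CPM and with the deposited library sizes. With total counts alone 6 members were higher and 1 lower, the list's median was 0.05 and its call was lost (camera adjusted p = 0.260), as were those of Myl3, Myl2, Tpm1 and Myh6. Relative to the median of all genes the contractile median was -0.25 under both scalings. The match arises by construction, since a change of scaling moves all genes nearly alike, and does not restore the lost calls.

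Hypertrophy and stress markers were called higher, with 6 of 17 higher, 0 lower and 11 not called (6 and 0 adjusted over the list alone; median 0.26, camera adjusted p = 1.26e-06), and the call was lost at an adjusted p = 0.392 with an estimated correlation. The members that rose were not the natriuretic peptides. They included Fhl1, a four-and-a-half LIM domain protein gene, at 1.44 ± 0.18, the ubiquitin hydrolase gene Uchl1 at 1.75 ± 0.26, the intermediate filament gene Vim at 0.98 ± 0.14 and filamin C, Flnc, at 0.69 ± 0.16 (edgeR adjusted p = 3.06e-05, 0.000144, 0.000115 and 0.00842). Flnc lost its call without control 1 or ISO+L-NAME 3 (0.0553 and 0.0655). Acta1 was carried by single hearts, with 124, 355 and 1067 counts in the treated libraries, and its log2 difference was -0.94 without ISO+L-NAME 3.

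Calcium handling was not called (1 higher and 1 lower of 17; 4 and 3 adjusted over the list alone; median 0.07, camera adjusted p = 0.849). With total counts alone, 8 members were higher and 0 lower, with a median of 0.38. The calcium pump gene Atp2a2 and its inhibitor Pln differed by 0.07 ± 0.10 and -0.07 ± 0.11 without passing (edgeR adjusted p = 0.788 and 0.824). Total counts alone called Atp2a2 higher and turned Pln positive. Hrc changed by -0.56 ± 0.11 and the ryanodine receptor gene Ryr2 by 0.43 ± 0.10 (edgeR adjusted p = 0.00225 and 0.0154). Total counts ended the Hrc call, and Ryr2 lost its call without control 1, control 2 or ISO+L-NAME 2 (0.0624 to 0.147). Cardiac ion channels were not called (1 higher and 2 lower of 16; 3 and 4 adjusted over the list alone; camera adjusted p = 0.258, or 0.0379 without control 3). Kcnip2, a subunit of the transient outward potassium channel, fell from 366 ± 28.9 to 189 ± 32.5 CPM (SD, n = 3; log2 -0.95 ± 0.12, edgeR adjusted p = 3.18e-05).

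Nitric oxide and cyclic GMP genes were not called (0 of 12 changed, also adjusted over the list alone; median -0.05, mean 0.02, camera adjusted p = 0.917 with direction down), and Nos3, endothelial nitric oxide synthase, differed by -0.44 ± 0.26 (edgeR adjusted p = 0.410). Beta-adrenergic signalling was not called (1 of 21 higher, 0 lower, the same adjusted over the list alone, camera adjusted p = 0.119). Camera did call it with total counts alone (0.0495) and without control 1 (0.0469). Total counts gave 10 members higher and 0 lower, with a median of 0.46 against 0.15 in the main fit. The receptor kinase gene Grk5 rose by 1.15 ± 0.21, and Adrb1 differed by -0.55 ± 0.20 (edgeR adjusted p = 0.00146 and 0.120). Renin-angiotensin-aldosterone and endothelin genes were not called (2 of 6 higher, 0 lower, the same adjusted over the list alone; camera adjusted p = 0.178). The endothelin receptor gene Ednra rose by 0.86 ± 0.18 and Ace by 1.16 ± 0.30 (edgeR adjusted p = 0.00513 and 0.0217). Ednra lost its call without control 1 (0.0567) and Ace without control 1, ISO+L-NAME 2 or ISO+L-NAME 3 (0.0567 to 0.149) and with DESeq2.

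Day-phase clock genes rose, with 8 of 12 higher, 0 lower and 4 not called (11 and 0 adjusted over the list alone; median 0.86, camera adjusted p = 7.65e-17). This call ended at an adjusted p = 0.150 with an estimated correlation, and fry kept it. Dbp, a clock-controlled transcription factor gene, rose from 18.8 ± 3.68 to 74.9 ± 10.8 CPM (SD, n = 3; 4.01-fold, SE 0.17 on the log2 scale, edgeR adjusted p = 4.23e-07). Per2, Tef and the clock repressor gene Ciart rose by 2.02 ± 0.30, 0.83 ± 0.13 and 3.10 ± 0.45 (edgeR adjusted p = 0.000183, 0.000390 and 0.000115). Without control 3, Ciart was higher by 3.75. Opposite-phase clock genes were not called (0 of 3 changed, also adjusted over the list alone, camera adjusted p = 0.923). The members Arntl, Npas2 and Nfil3 had too few counts to be tested. The labels give no time of collection.

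Glucocorticoid targets were called higher, with 4 of 11 higher, 0 lower and 7 not called (5 higher and 1 lower adjusted over the list alone; median 0.49, camera adjusted p = 0.000371). The call was lost at an adjusted p = 0.513 with an estimated correlation. The metallothionein genes Mt1 and Mt2 rose by 1.38 ± 0.18 and 2.82 ± 0.33 (edgeR adjusted p = 5.62e-05 and 1.22e-05), though the robust fit called neither (0.119 and 0.117). Per1, also a clock gene, rose by 0.85 ± 0.20 and Fkbp5 by 1.04 ± 0.30 (edgeR adjusted p = 0.00989 and 0.0419). Per1 lost its call without control 1 or ISO+L-NAME 1 (0.0629 and 0.0594), and Fkbp5 without control 1, control 2, ISO+L-NAME 2 or ISO+L-NAME 3 (0.0837 to 0.277) and in the robust, DESeq2 and voom fits. Oxidative stress and NRF2 targets, a list that also holds Mt1 and Mt2, were called higher with 4 of 21 higher, 1 lower and 16 not called (7 and 2 adjusted over the list alone; median 0.14, camera adjusted p = 0.00263), and the call was lost at an adjusted p = 0.150 with an estimated correlation. The glutathione peroxidase genes Gpx3 and Gpx1 rose by 0.90 ± 0.16 and 0.70 ± 0.13, and Txnip, which binds thioredoxin, changed by -0.76 ± 0.11 (edgeR adjusted p = 0.000853, 0.00189 and 0.000163).

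Immediate early genes were called higher, with 2 of 14 higher, 0 lower and 12 not called (6 higher and 1 lower adjusted over the list alone; median 0.29, camera adjusted p = 0.0360). The call did not hold at an adjusted p = 0.738 with an estimated correlation, without control 2 (0.265), control 3 (0.111) or ISO+L-NAME 1 (0.977), and with total counts (0.213). Ier3 rose by 1.34 ± 0.19 and Jun by 1.28 ± 0.34 (edgeR adjusted p = 0.000105 and 0.0240), while Junb and Atf3 differed by 0.88 ± 0.28 and 2.54 ± 0.83 without passing (0.0703 and 0.0785). Jun had 490 counts in ISO+L-NAME 1 and 150 and 104 in the other treated libraries. Without ISO+L-NAME 1 its log2 change was 0.45 (edgeR adjusted p = 0.236) and that of Atf3 -0.02. Total counts and an unfiltered fit called both Junb and Atf3. Junb also passed without ISO+L-NAME 3 (0.0223), and Atf3 without ISO+L-NAME 2 or ISO+L-NAME 3 (0.0388 and 0.00804) and with the replicate block. Jun also lost its call without each control library (0.0543 to 0.0925) and in the robust, DESeq2 and voom fits.

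The unfolded protein response was not called (1 higher and 4 lower of 17; 5 and 5 adjusted over the list alone; camera adjusted p = 0.923), its median and mean of 0.13 and camera's direction differing in sign. Calr, Manf and Xbp1 changed by -0.52 ± 0.12, -0.84 ± 0.20 and -0.62 ± 0.18 (edgeR adjusted p = 0.00752, 0.0136 and 0.0372), and Atf6, the single member called higher, by 0.57 ± 0.15 (0.0287). Total counts ended the 3 lower calls and gave 5 members higher and 0 lower, with a median of 0.43. Xbp1 lost its call in each of the 6 fits without 1 library (0.0587 to 0.115) and with DESeq2, Manf without control 2, control 3 or ISO+L-NAME 3 (0.0514 to 0.0852) and Calr without ISO+L-NAME 2 (0.0680). Heat shock genes were not called (1 higher and 2 lower of 12, the same adjusted over the list alone; camera adjusted p = 0.763), with the small heat shock protein genes Hspb8 at -0.74 ± 0.11 and Hspb7 at 0.72 ± 0.14 (edgeR adjusted p = 0.000154 and 0.00289). Muscle atrophy and FoxO targets were not called (2 of 16 higher, 0 lower; 3 and 0 adjusted over the list alone; camera adjusted p = 0.158, or 0.0123 with total counts). The mitophagy gene Bnip3 rose by 0.95 ± 0.12 and Map1lc3a by 0.39 ± 0.11 (edgeR adjusted p = 2.53e-05 and 0.0330), the second call being lost in every fit without 1 library except ISO+L-NAME 1 (0.0670 to 0.195).

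Cytosolic ribosomal protein genes were called lower with a median of -0.10 (1 higher, 1 lower and 74 of 76 not called; 0 and 0 adjusted over the list alone; camera adjusted p = 0.0133). Camera dropped the list at an adjusted p = 0.668 with an estimated correlation and without ISO+L-NAME 1 or ISO+L-NAME 2 (0.0517 and 0.0841), and total counts, which moved all genes, gave a median of 0.21 (0.181). Relative to the median of all genes it was -0.09 under both scalings, which a near-uniform shift gives by construction. Rpl36 and Rps13 changed by -0.35 ± 0.10 and 0.37 ± 0.11 (edgeR adjusted p = 0.0496 and 0.0440), while Rps14, Rps15 and Rplp2 differed by -0.29 ± 0.10, -0.25 ± 0.10 and -0.24 ± 0.10 without passing (0.0871, 0.184 and 0.206). Rpl36 lost its call in every fit without 1 library except control 2 (0.0844 to 0.211), with RLE scaling, total counts, DESeq2, no filter, the replicate block and mitochondrial genes left out, and Rps13 in all 6 (0.0566 to 0.192) and with the deposited library sizes. Ribosomal proteins have many processed copies that could share reads.

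Among markers of other cells, red cell markers were not called (0 of 7 changed, also adjusted over the list alone; camera adjusted p = 0.150, or 0.00964 without control 3 and 0.0481 without ISO+L-NAME 1), with 0.474% ± 0.0559 of counts in controls and 0.497% ± 0.0720 in treated hearts (SD, n = 3; two-sided exact permutation p = 0.7). Their globin genes are near-identical copies. Atrial markers were not called (1 of 5 lower, 0 higher; 1 and 1 adjusted over the list alone; camera adjusted p = 0.880), with Stard10 at -0.88 ± 0.21 (edgeR adjusted p = 0.0122), a call lost without control 3 or ISO+L-NAME 3 (0.0543 and 0.0647) and with total counts. Schwann cell and nerve markers were not called (1 higher and 1 lower of 3, the same adjusted over the list alone; median 0.15, mean -0.20, camera adjusted p = 0.923). Pmp22 rose by 0.67 ± 0.17 (edgeR adjusted p = 0.0219), lost without control 2, control 3, ISO+L-NAME 2 or ISO+L-NAME 3 (0.0745 to 0.0957) and with DESeq2. Adipocyte markers were not called (0 of 3 changed, also adjusted over the list alone; median 0.04, mean -0.0093, camera adjusted p = 0.926). Skeletal muscle, lung epithelium and epicardium markers had 0 tested members, with 19, 1 and 107 counts over the control libraries and 9, 7 and 71 over the treated ones. Among the last, picked out after the counts were seen, the mesothelial genes Msln and Upk3b had 4, 0, 8 and 3, 3, 11 counts in controls against 0, 0, 0 and 0, 1, 0 in treated hearts. Upk1b had 4, 0, 4 against 0, 0, 0 and Lrrn4 had 2, 1, 1 against 0, 0, 0, while Tbx18 had 9, 10, 7 against 24, 7, 6. Lymphocyte markers had 1 tested member, cell cycle genes 2 and nuclear-retained RNAs 1, Snhg11.

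**Figure D2:**
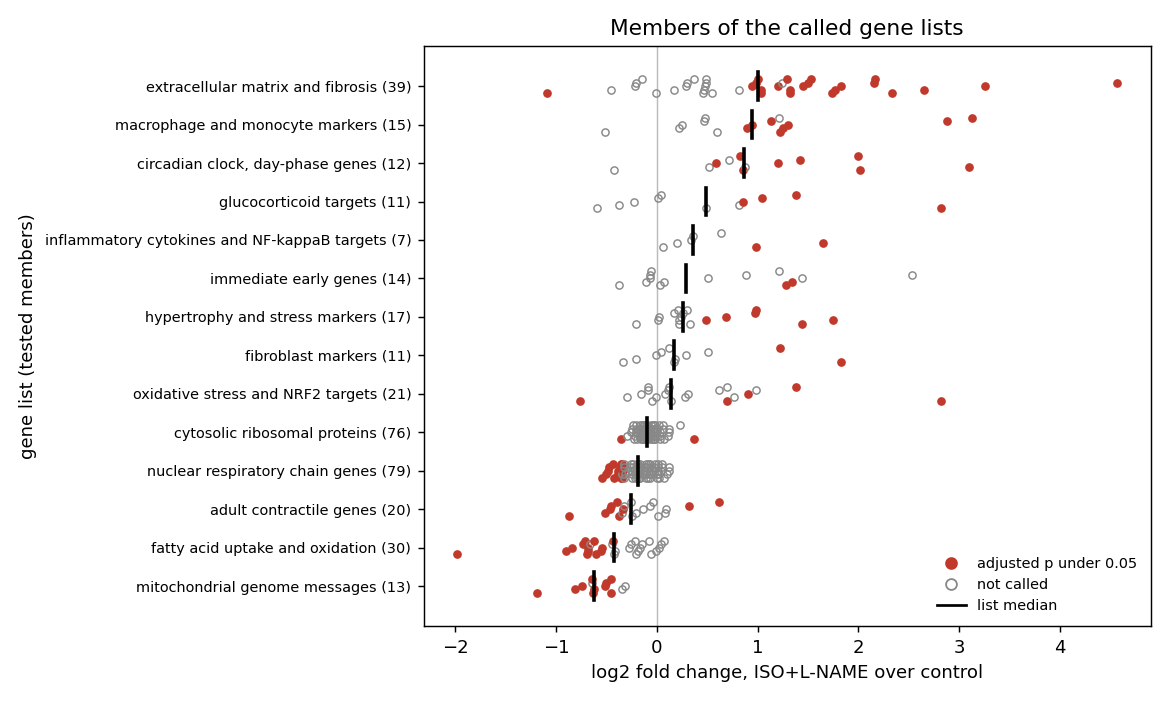
Log2 fold changes (ISO+L-NAME over control) of the tested members of the 14 called lists, 1 point per gene, filled where the edgeR adjusted p was under 0.05, with a black bar at each list's median. Medians run from -0.62 for mitochondrial genome messages to 1.00 for extracellular matrix genes; with total counts alone, those of the contractile, respiratory chain and ribosomal lists turned positive.

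The libraries differed in composition along the group boundary. The 10 most abundant genes, 9 of them mitochondrial, took 54.1% ± 1.41 of counts in controls and 46.9% ± 1.24 in treated hearts, and genes detected numbered 12507 ± 83.1 and 12861 ± 149 (SD, n = 3; two-sided exact permutation p = 0.1 for both). Ribosomal protein genes took 2.13% ± 0.0619 and 2.47% ± 0.110 of all counts (exact permutation p = 0.1), and 4.75% ± 0.0665 and 4.65% ± 0.147 of counts outside the mitochondrial genome (exact permutation p = 0.4). Total counts did not separate the groups (exact permutation p = 0.4). Counts outside the mitochondrial genome did, with 1016859 to 1101936 in controls and 1229798 to 1438272 in treated hearts (exact permutation p = 0.1). Genes detected were therefore not compared at equal nuclear depth.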

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

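The deposited library sizes were chosen as an alternative after seeing the data. Of the 520 changed genes, 510 were also called with RLE scaling, 512 with the deposited sizes, 480 with voom and 335 with DESeq2. The deposited sizes were 1.11 to 1.13 times the TMM-adjusted ones in all libraries, so their overlap with the main fit was nearly fixed beforehand. Signs were compared only for genes called in both fits (363 with total counts alone), and 0 of these were opposite under any alternative. Total counts alone called 1479 genes (1407 higher, 72 lower) and 2 lists lower, and turned the ribosomal list (camera adjusted p = 0.181). The median log2 change of all genes was 0.30 with total counts and -0.0075 in the main fit. Which of these scalings is nearer the truth was not tested, and the direction of the contractile, respiratory chain and ribosomal medians depends on it. DESeq2 called 335 genes, 138 of them lower. Leaving out 1 library gave 301 to 494 changed genes, 179 to 272 higher and 122 to 222 lower, and 4 to 8 lists lower; fewer samples were fitted. No filter gave 8 lists lower. An estimated correlation gave 0 lists (0 higher, 0 lower) and fry 5 (2 higher, 3 lower). The cause was not tested. The estimated correlation was 0.41 for the matrix list and 0.71 for the mitochondrial one, above the preset 0.01. For the oxidative stress list it was -0.0082, under the preset, so a higher correlation cannot explain the loss of that call. Over counts outside the mitochondrial genome, the group difference was -0.108 points for ribosomal and -0.125 for red cell genes, by the change of denominator. For the 10 most abundant nuclear genes it was -1.49, with both the genes and the denominator changed. Replicate numbers did not pair the hearts: deviations of same-numbered libraries correlated at 0.061, -0.028 and -0.014, and not every library correlated best with its own number. The replicate block called 560 genes (319 higher, 241 lower) and 14 lists. In the simulated counts, with 3 against 3 libraries and 200 changed genes, a 1.5-fold change was mostly missed. Depth and the number of libraries were not varied there.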

Other observations

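The genes and the complement list of this paragraph were chosen after their values were seen. Of 15 tested complement genes, 9 were higher and 0 lower (13 and 0 adjusted over the list alone), with a median log2 change of 0.90. C3, the central complement protein, rose by 1.26 ± 0.14, C4b by 1.46 ± 0.34 and the C3a receptor gene C3ar1 by 1.58 ± 0.40 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 1.14e-05, 0.0105 and 0.0194). The regulators Serping1 and Clu rose by 0.91 ± 0.12 and 0.93 ± 0.12 (adjusted p = 4.30e-05 and 2.53e-05 in the same test). C1qb and C1qc are in both this list and the macrophage list. Among genes outside all lists, Nudt4, Ctnnal1, Tent5a and Fgl2 rose by 1.60 ± 0.13, 2.05 ± 0.20, 1.74 ± 0.17 and 1.94 ± 0.21. Slc6a6, the taurine transporter gene, rose by 1.13 ± 0.12, beside the increase of Cdo1, whose enzyme acts upstream in taurine synthesis. Actr3b and the mitochondrial carrier gene Slc25a34 changed by -1.36 ± 0.17 and -0.94 ± 0.12.

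Of the tests in the paragraphs that follow, only that of Arntl and Npas2 was written before its result was seen; the others were chosen after. The 3 against 3 design has 10 splits, too few for a share under 0.05. The real split called 520 genes and the highest other split 0, with 1 split as large, the real one. For gene lists the real split called 14 and the highest other split 13, with 1 split as large, the real one.

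The lower mitochondrial messages were set against 3 explanations. The TMM scaling as the whole cause is argued against by the unscaled share of counts, which differed by -8.25 percentage points without overlap. A lower share of cardiomyocytes as the whole cause would move contractile and calcium-handling genes as far, but the mitochondrial median lay below theirs by -0.48 (bootstrap 95% interval over genes -0.66 to -0.21). The contractile median was itself -0.26 and the calcium-handling one 0.07, so a smaller part from cell makeup is not excluded. An equal fall in the counts of all 13 genes is argued against by unequal changes, from -1.19 for mt-Nd4l to -0.31 for mt-Nd2 (chi-square heterogeneity p over 13 genes, from edgeR's quasi-likelihood estimates, = 3.54e-09). The extreme gene, mt-Nd4l, overlaps mt-Nd4, which changed by -0.64. Reads may be shared, so its value may not be that of a separate message. The test was not run without it. Other explanations were not tested and stay open.

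The higher matrix genes were set against 2 changes of cell makeup. A lower share of cardiomyocytes as the whole cause would raise endothelial and mural markers alike. The matrix median of 39 genes exceeded that of 32 such markers by 1.12 (bootstrap 95% interval 0.60 to 1.54). More resident fibroblasts as the whole cause would raise fibroblast markers outside the matrix list as far. The matrix median exceeded that of 9 such genes by 0.88 (0.32 to 1.26). These 9 leave out Mfap5 and Dcn, fibroblast markers held also by the matrix list. Mfap5 rose by 1.83, and Dcn differed by 0.29 without passing. The difference of medians does not exclude more fibroblasts as a part of the cause. Other explanations were not tested and stay open.

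The higher day-phase clock genes may reflect another time of day at collection. That explanation needs Arntl and Npas2, which run opposite to Dbp, to be lower. By the test written in advance their summed counts were lower, with log2 -1.87 (95% interval -2.84 to -0.90). They were 17, 13 and 5 in controls and 1, 4 and 7 in treated hearts, and these ranges overlap. The row lay under the count filter and was fitted without it. A fit without the filter can understate the spread between hearts. It gave Atf3, whose groups overlap, an edgeR adjusted p of 1.57e-16, against 0.0785 in the main fit. The interval therefore does not settle whether the summed counts were lower. The difference lay in Arntl (14, 11 and 5 against 0, 4 and 4), while Npas2 had 3, 2 and 0 against 1, 0 and 3. The opposite-phase list set in advance was not called (0 of 3 changed, camera adjusted p = 0.923). The count filter had left Arntl, Npas2 and Nfil3 out of its tested members, so that result does not cover them. Nfil3 had 17, 6 and 6 counts in controls and 10, 13 and 9 in treated hearts. A treatment that shifts the clock would give the same values and the labels give no collection time, so the cause stays open.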
